A study of Mus musculus with 8 samples.

How the data were processed

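RNA from CD8 T cells of 8 mouse groups was hybridized to 8 one-colour Agilent arrays on 1 slide, scanned together. The groups were taken from the labels, which give age, genotype and tumor, and each group has 1 array. Per the labels, tumor-bearing mice gave draining lymph nodes and tumor-free mice peripheral lymph nodes. The choices below were made before the data were examined, except where stated otherwise.

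Per the file headers, the authors' processed signal (gProcessedSignal) is a background-subtracted, spatially detrended spot intensity of 1 array on a linear scale, made with Agilent Feature Extraction 11.0.1.1 and not scaled between arrays. Per the file headers, the median spot signal and the median local background are raw intensity values. The deposited flags are of the unit other: 0 or 1 per spot, marking spots well above background, saturated or non-uniform. The deposited value table is in log2 and holds 23971 probes. All 8 columns of that table have the same median, 9.10327, which shows log2 values scaled between arrays. They correlate with log2 of the processed signal at r of 0.99966 or more. Equal medians do not tell quantile normalization from another scaling, and the authors' steps are not stated. All columns of the table were mapped to a sample.

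The processed signal was taken to log2 and the 75th percentile of each array was subtracted. Of 56605 non-control probes, 12 were dropped for a flagged spot and 27247 were kept as well above background on at least 4 of 8 arrays. Symbols came from a RefSeq table, which named 32994 probes; the other 23611 kept the name in the files. For each gene the probe of highest mean over all arrays was used, which left 21232 features, 12823 with a symbol. No coordinates are given, since the file headers name an older mouse build than the gene table; chromosomes come from the gene table. The signal at the 75th percentile ran from 292 to 383 and 46.4% to 49.5% of probes were well above background.

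Each feature was fitted with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8) with age, genotype and tumor as additive terms, which puts 4 arrays against 4 for each factor. With 1 array per group, the error comes from departures from additivity (4 residual degrees of freedom, prior degrees of freedom 2.70). Interactions were tested in a model with all 3 pairwise interactions (1 residual degree of freedom, prior 3.27). With an array left out, they were fitted with the 3 factors and the tested interaction alone. P-values were 2-sided and adjusted by Benjamini and Hochberg over all features within each comparison, with a threshold of 0.05. Where no array of one level had a gene well above background, the fold was computed as a lower bound against the lowest signal that was well above background.

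Lists of genes fixed before the data were examined, 30 of T cell programs and metabolism and 13 of cell type markers, were tested with limma's camera at a preset correlation of 0.01. The adjustment ran over the 40 lists with at least 5 measured genes, and camera with an estimated correlation and fry were run beside it. Camera compares a list with other genes, whereas fry tests whether a list's genes move on balance to one side. List interactions, the test of chromosomes and the covariate of macrophage genes were chosen after the data were seen.

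The genes named were the 10 largest rises and the 10 largest falls among symbols past the threshold with the same sign in all 4 pairs of arrays that differ in that factor alone. Where none passed, the 5 largest each way with the same sign in all 4 pairs were named as not passing. Pdcd1 was always named, and up to 4 members of the largest absolute change from each list described. Predicted genes, clone names and transcript identifiers were counted but not named. Cd8a, Hba-a1, Hbb-bt, Cd163l1, Xist, Ddx3y, Itgam, Apoe, Lcn2 and Ncr1 were chosen after their values were seen.

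The steps were tested on simulated data for the same 21232 features. Changes of 1 and 2 on the log2 scale, 100 features each, were recovered for 60% and 94% (age), 54% and 89% (tumor) and 56% and 85% (genotype), with 5, 12 and 6 false calls, and 5 of 5 changed lists were recovered with 0 false. The simulated genes varied independently, while genes of some measured lists move together (estimated correlation up to 0.906, for cell cycle). The 0 false lists therefore do not carry over to such lists. Interactions of 2 in 200 features were recovered for 0% in each of the 3 tests, and those with genotype were simulated only after the data were seen.

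Alternatives tried were quantile normalization, no scaling, normexp background correction (offset 50) on the median signal, since the files hold no mean signal, other filters and none, the mean of a gene's probes, the authors' values, other models, array weights, an intensity trend, B cell and macrophage covariates, features with a symbol alone, and each array left out in turn. Control spots, the lists with fewer than 5 measured genes in the list tests, and tests of any single group against another were left out; the latter were not run, since each group has 1 array.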

Results

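Gene expression was measured on 8 Agilent mouse arrays, each holding RNA from CD8 T cells isolated from lymph nodes with CD8a beads. The mice were young (2 months) or aged (17 months), wild type (WT) or labelled PD-1KO (lacking PD-1, the inhibitory T cell receptor encoded by Pdcd1), and either tumor-free or taken 9 days after inoculation with MC38, a mouse colon carcinoma line. Each of the 8 groups formed by age, genotype and tumor had 1 array, so no group had a replicate. Each level of a factor had 4 arrays, the differences below are log2 values with their standard error (SE) over 4 arrays against 4, and the number of arrays limits their precision. Between 26276 and 27996 probes per array were well above background, and no spot was saturated. Of the features on the array, 21232 were tested, 12823 of them with a gene symbol. The correlation of log2 signal across features between arrays ran from 0.958 to 0.995, where features are not independent replicates. In a principal component analysis, component 1 held 41.7% of the variance and placed the young arrays between -41.9 and -34.3 and the aged arrays between 13.6 and 66.6.

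Pdcd1 itself was read by 1 probe, which was well above background on all 8 arrays, those of mice labelled PD-1KO included. Whether that probe lies in the deleted part of the gene is not known, so its level does not test the genotype labels. Its log2 level relative to the 75th percentile of the array was -0.79 in Young_WT, 1.03 in Young_WT with tumor, -1.45 in Young_PD-1KO, -0.35 in Young_PD-1KO with tumor, -0.10 in Aged_WT, 2.73 in Aged_WT with tumor, 1.87 in Aged_PD-1KO and 2.74 in Aged_PD-1KO with tumor. Pdcd1 rose with age by 2.20 (SE 0.49, adjusted p = 0.0421), in 4 of 4 pairs of arrays that differ in age alone. This call was lost when any array other than Aged_WT was left out. The difference with tumor was 1.65 (SE 0.49, adjusted p = 0.15), in 4 of 4 pairs, and the difference with genotype was -0.02 (SE 0.49, adjusted p = 0.991), with 2 of 4 pairs above 0; neither passed.

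The comparison of aged with young mice addresses how age acts on CD8 T cell expression. Aged arrays had higher levels of NK cell receptor, cytotoxicity and inhibitory receptor genes and lower levels of genes of naive T cells by camera with a preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.146, 0.146, 0.177 and 0.371 with an estimated correlation), and 16 of the 20 naive genes did not pass singly. S1pr5, a sphingosine-1-phosphate receptor of effector and NK cells, rose by 3.80 (SE 0.37, adjusted p = 0.00621). Klra2, a receptor of the Ly49 family, was at least 4.41-fold higher in aged arrays, as no young array had it well above background (adjusted p = 0.0122). Sox4, a transcription factor of naive and developing T cells, fell by 1.93 (SE 0.28, adjusted p = 0.0168). The marker lists of macrophages, neutrophils, B cells and plasma cells were also higher on the aged arrays, with medians of 1.47, 1.85, 0.51 and 1.42 (adjusted p = 0.369, 0.233, 0.371 and 0.233 with an estimated correlation). In limma, 2289 of 21232 features changed with age, 1323 of them higher and 966 lower in aged mice, and 1490 of them had a gene symbol (834 higher, 656 lower).

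The genes with the largest rises were led by Myom2, a protein of the muscle sarcomere, which was at least 21.9-fold higher in aged arrays, being well above background on 4 aged arrays and on 0 young arrays (adjusted p = 0.0029). Tnfsf4, which encodes OX40 ligand, was at least 7.27-fold higher, Dpysl5 at least 7.23-fold higher and Acod1, the enzyme that makes itaconate, at least 5.61-fold higher, again with 0 young arrays well above background. Ret, a receptor tyrosine kinase, rose by 4.21 (SE 0.70), Esm1 by 4.09 (SE 0.89), Lmo1 by 3.82 (SE 0.44) and the immediate early gene Ier3 by 3.73 (SE 0.36). The largest fall was that of Cmtm2b, which was at least 5.97-fold lower in aged arrays and well above background on 0 of them. Mc3r, a melanocortin receptor, fell by 2.91 (SE 0.20), Grm6, a metabotropic glutamate receptor, fell by 2.35 (SE 0.36), Xkrx fell by 2.28 (SE 0.41), Bambi-ps1 fell by 2.24 (SE 0.40) and Amigo2 fell by 2.19 (SE 0.37). Atp1b1, a subunit of the sodium pump, fell by 2.09 (SE 0.49), while Gria3 was at least 1.69-fold lower and Abcb11, the bile salt export pump, at least 1.27-fold lower. All of these genes moved the same way in 4 of 4 pairs, as the rule for naming genes required. Ret (1 young and 3 aged arrays), Mc3r (4 and 1), Grm6 (4 and 2) and Amigo2 (4 and 2) were not well above background on every array, so their sizes rest in part on background. Over the genes with the largest rises and falls, the adjusted p ran from 0.00217 for Mc3r to 0.0451 for Atp1b1. The calls of Abcb11, Amigo2, Atp1b1, Bambi-ps1, Esm1, Gria3, Grm6, Klra2, Ret, Sox4 and Xkrx were each lost when at least 1 of the arrays was left out. Of the named genes other than Pdcd1, 11 lost their call without Young_WT with tumor, 10 without Aged_PD-1KO, 9 without Young_PD-1KO with tumor, 8 without Young_WT, 6 without Aged_PD-1KO with tumor, 3 without Young_PD-1KO, and 1 each without Aged_WT and without Aged_WT with tumor, with no change of sign.

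**Figure D1:**
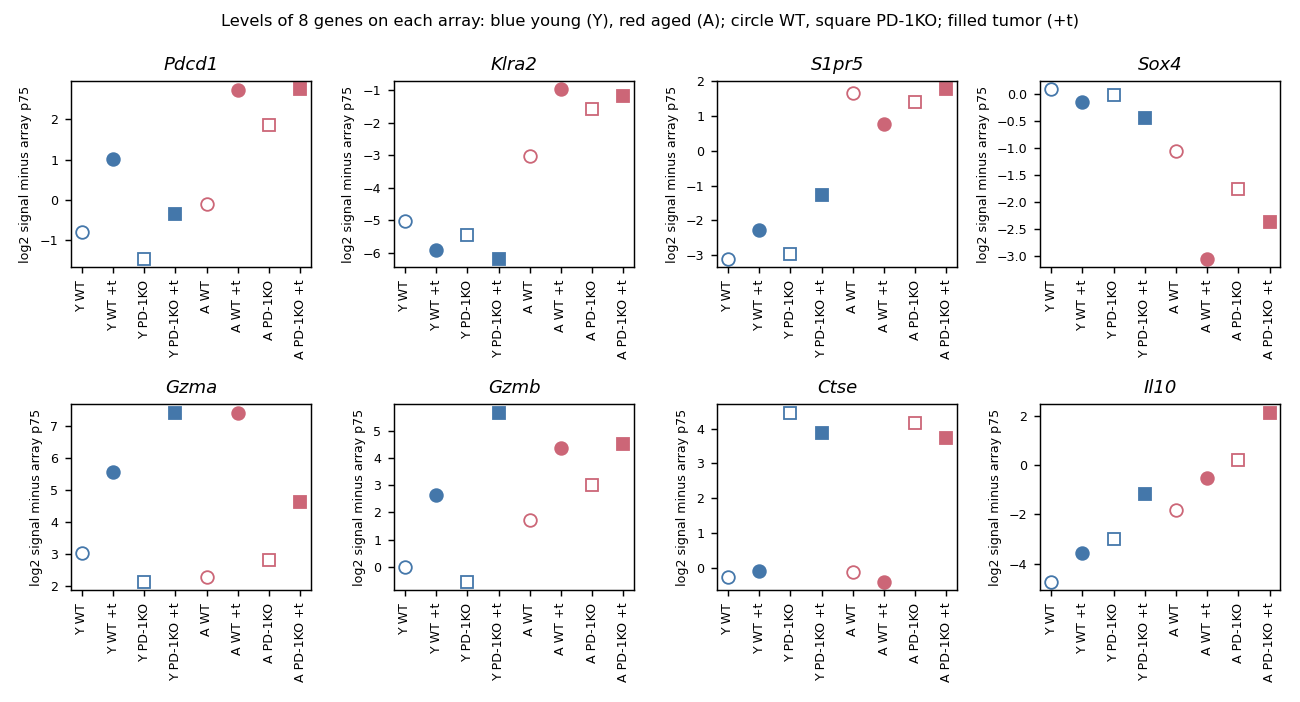
Levels of 8 genes on each of the 8 arrays (x axis), as log2 signal minus the 75th percentile of the array (y axis), with young arrays in blue, aged in red, WT as circles, PD-1KO as squares and tumor-bearing mice as filled symbols; each point is 1 array, so there are no error bars. Pdcd1, Klra2, S1pr5 and Il10 were higher and Sox4 lower with age, Ctse and Il10 were higher with the PD-1KO label, and Gzma and Gzmb were higher with tumor without passing the test.

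Among gene groups, NK receptors gave the largest shift of the T cell programs. Of 18 measured NK receptor genes, 13 rose, 0 fell and 5 did not pass (adjusted over the list alone, 13 rose and 0 fell), with a median log2 change of 1.71 and Klra8 at 2.64, Klra10, well above background on 1 young array, at 2.34 and Klrb1f at 2.02 (camera adjusted p = 2.13e-09, adjusted p = 0.146 with an estimated correlation). Of 20 genes of cytotoxicity and effector cytokines, 12 rose, 0 fell and 8 did not pass (adjusted over the list alone, 13 rose and 1 fell). Their median was 0.87, and the granzyme gene Gzmk rose by 3.50, the death ligand gene Fasl by 2.50 and the chemokine genes Ccl4 and Ccl3 by 2.46 and 2.41 (camera adjusted p = 1.13e-08, adjusted p = 0.146 with an estimated correlation). Of 21 genes of inhibitory receptors and exhaustion, 11 rose, 0 fell and 10 did not pass (adjusted over the list alone, 14 rose and 0 fell). Their median was 1.05, with Entpd1 (CD39) at 2.41, Casp4 at 2.18 and Lag3 at 1.95 (camera adjusted p = 9.52e-09, adjusted p = 0.177 with an estimated correlation). Of 31 effector and memory genes, 10 rose, 0 fell and 21 did not pass (adjusted over the list alone, 17 rose and 0 fell). Their median was 0.51, and the transcription factor genes Bhlhe40, Prdm1 and Eomes rose by 1.91, 1.64 and 1.64 (camera adjusted p = 9.52e-09, adjusted p = 0.285 with an estimated correlation). On the same arrays the macrophage, neutrophil, B cell and plasma cell lists had median shifts of 1.47, 1.85, 0.51 and 1.42.

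Genes of inflammation and senescence were also higher in aged arrays, 9 of 21 having risen, 0 fallen and 12 not passed (adjusted over the list alone, 12 rose and 2 fell). Their median was 0.83, and the cytokine genes Il10 and Il21 rose by 3.11 and 2.74, Spp1 by 2.68 and Ccl8 by 2.30, with Il10 and Spp1 well above background on 2 and Il21 on 1 of the young arrays (camera adjusted p = 1.63e-05, adjusted p = 0.146 with an estimated correlation). Of 23 genes of the p53 and DNA damage response, 6 rose, 2 fell and 15 did not pass (adjusted over the list alone, 9 rose and 3 fell). Phlda3, Perp and Pmaip1, all p53 targets, rose by 1.83, 1.54 and 0.93, while the cell cycle inhibitor Cdkn1a stood at 0.83 without passing; the list median was 0.14 (camera adjusted p = 0.0182, adjusted p = 0.233 with an estimated correlation). Without Young_PD-1KO with tumor the p53 list had a median of 0.14 and was not called. The macrophage, neutrophil, B cell and plasma cell lists moved on the same arrays by medians of 1.47, 1.85, 0.51 and 1.42.

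Several groups were lower in aged mice by smaller amounts. Of 20 genes of naive and quiescent T cells, 0 rose, 4 fell and 16 did not pass (adjusted over the list alone, 1 rose and 15 fell). Their median was -0.44, Sox4 was among those that fell, and Ramp1 at -1.90, Igfbp4 at -1.54 and Dapl1 at -1.46 did not pass (camera adjusted p = 3.87e-05, adjusted p = 0.371 with an estimated correlation). Of 40 genes of ribosome biogenesis, 0 rose, 10 fell and 30 did not pass (adjusted over the list alone, 0 rose and 24 fell). Their median was -0.33, with Wdr74 at -0.77 and Nop16 at -0.61 (camera adjusted p = 8.78e-07, adjusted p = 0.334 with an estimated correlation). Of 23 cholesterol biosynthesis genes, 0 rose, 5 fell and 18 did not pass (adjusted over the list alone, 0 rose and 11 fell). Their median was -0.41, with Fdps at -0.75 (camera adjusted p = 0.000162, adjusted p = 0.546 with an estimated correlation). Of 20 genes of DNA and histone methylation, 0 rose, 4 fell and 16 did not pass (adjusted over the list alone, 0 rose and 4 fell). Their median was -0.24, and the DNA demethylase gene Tet1 stood at -1.35, the DNA methyltransferase gene Dnmt3a at -0.69 and Suv39h1 at -0.55 (camera adjusted p = 0.0182, adjusted p = 0.285 with an estimated correlation). Without Aged_PD-1KO with tumor that list, at -0.24, was not called. While these groups were lower, the macrophage, neutrophil, B cell and plasma cell lists were higher by medians of 1.47, 1.85, 0.51 and 1.42.

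Of the metabolic groups, 4 more were lower in aged arrays, by camera with a preset correlation, and 3 did not pass. Of 33 genes of the TCA cycle and mitochondrial biogenesis, 0 rose, 4 fell and 29 did not pass (adjusted over the list alone, 0 rose and 4 fell). Their median was -0.29, with the mitochondrial import gene Tomm40 at -0.52 (camera adjusted p = 0.000135, adjusted p = 0.371 with an estimated correlation). Of 26 one-carbon and serine metabolism genes, 1 rose, 4 fell and 21 did not pass (adjusted over the list alone, 2 rose and 10 fell). The purine synthesis gene Gart fell by 0.80, the serine hydroxymethyltransferase gene Shmt1 fell by 0.78, Gldc rose by 0.99, and the list median was -0.31 (camera adjusted p = 0.0237, adjusted p = 0.577 with an estimated correlation). Proteasome genes had a median of -0.22, with 1 of 32, Psmc4 at -0.47, having fallen, 0 risen and 31 not passed (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.00121, adjusted p = 0.659 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.14, with 2 of 67 having fallen, Ndufa10 at -0.58 among them, 0 risen and 65 not passed (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.0258, adjusted p = 0.858 with an estimated correlation). The call of the one-carbon list was lost without Young_PD-1KO with tumor (-0.19) and without Aged_PD-1KO with tumor (-0.26), and that of the oxidative phosphorylation list without those arrays (-0.09 and -0.13), Aged_WT with tumor (-0.10) or Aged_PD-1KO (-0.13). With the macrophage list mean as a covariate, the medians of the one-carbon, proteasome and oxidative phosphorylation lists turned to 0.05, 0.05 and 0.15, and the macrophage, neutrophil, B cell and plasma cell lists were higher by medians of 1.47, 1.85, 0.51 and 1.42 on the same arrays. The lists that did not pass were glycolysis at -0.10 (camera adjusted p = 0.523), fatty acid oxidation at -0.10 (camera adjusted p = 0.253) and amino acid transport with ATF4 targets, where the median was -0.10 and the mean 0.14 (camera adjusted p = 0.904). In this last list 2 of 23 genes rose, the asparagine synthetase gene Asns by 2.00 (SE 0.43, adjusted p = 0.0386) among them, and 1 fell.

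Markers of other cell types moved with age. Of 20 macrophage and monocyte genes, 12 rose, 0 fell and 8 did not pass (adjusted over the list alone, 19 rose and 0 fell). Their median was 1.47, with Ms4a7 at 2.07 and Itgam at -0.03 without passing (camera adjusted p = 9.2e-10, adjusted p = 0.369 with an estimated correlation). Of 9 neutrophil genes, 5 rose, 0 fell and 4 did not pass (adjusted over the list alone, 6 rose and 0 fell). Their median was 1.85, with S100a9 at 2.55, Retnlg, well above background on 1 young and 3 aged arrays, at 2.52 and Camp at 2.51 (camera adjusted p = 4.86e-05, adjusted p = 0.233 with an estimated correlation). Only 4 of these 9 genes were well above background on all 8 arrays. Lcn2, whose change is the median, was so on 5, so that median rests in part on background. Of 20 B cell genes, 6 rose, 0 fell and 14 did not pass (adjusted over the list alone, 10 rose and 0 fell). Their median was 0.51, with Cd22 at 2.01 and Ms4a1 at 1.38 (camera adjusted p = 8.38e-07, adjusted p = 0.371 with an estimated correlation). Of 6 plasma cell genes, 4 rose, 0 fell and 2 did not pass (adjusted over the list alone, 4 rose and 0 fell). Their median was 1.42, with the antibody joining chain gene Jchain at 2.09 and Mzb1 at 1.63 (camera adjusted p = 0.00191, adjusted p = 0.233 with an estimated correlation). Of 12 NK cell and innate lymphoid cell genes, 5 rose, 0 fell and 7 did not pass (adjusted over the list alone, 7 rose and 0 fell). Their median was 0.62, with Klre1 at 1.94 (camera adjusted p = 1.79e-05, adjusted p = 0.146 with an estimated correlation). Ncr1, also on the fixed NK cell list, was well above background on 0 arrays and was not tested. Of 19 dendritic cell genes, 2 rose, 1 fell and 16 did not pass (adjusted over the list alone, 6 rose and 2 fell). Their median was 0.39, with Clec9a at 1.14 and Ccr9, which T cells also express, at -1.92 (camera adjusted p = 0.0317, adjusted p = 0.399 with an estimated correlation). The dendritic cell median turned to -0.04 with the macrophage list mean as a covariate, and the list was not called without Young_PD-1KO with tumor (0.30) or Aged_PD-1KO with tumor (0.22). Of 16 core genes of CD8 T cells, 0 rose, 1 fell and 15 did not pass (adjusted over the list alone, 0 rose and 1 fell). Their median was -0.24, with Trat1 at -1.14 (camera adjusted p = 0.0317, adjusted p = 0.505 with an estimated correlation). Without Aged_WT with tumor the core list, at -0.19, was not called. Other lists hold 8 of the 12 NK cell, 3 of the 6 plasma cell, 6 of the 19 dendritic cell and 1 of the 20 macrophage genes. The level of Cd8a itself ran from 4.22 to 4.97 over the 8 arrays, and the CD4 T cell list, with a median of 0.03, did not pass (camera adjusted p = 0.494). Of the hemoglobin genes, Hbb-bt, well above background on 1 young and 4 aged arrays, rose with age by 3.71 (SE 0.91, adjusted p = 0.0489), while Hba-a1 at 2.41 and Hba-a2 at 2.50 did not pass (adjusted p = 0.113 and 0.11), each in 4 of 4 pairs. They were highest on the Aged_WT array, where Hba-a1 was at 4.19 against -2.47 to 0.55 on the other arrays. The call of Hbb-bt was lost when any array other than Aged_PD-1KO was left out, and its rise was 2.77 without Aged_WT. The X-linked gene Xist rose with age by 0.74 (SE 0.16, adjusted p = 0.0388) in 4 of 4 pairs, and this call was lost when any array other than Aged_WT or Aged_WT with tumor was left out.

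Of 40 lists tested for age, camera with a preset correlation called 21, 12 higher and 9 lower, fry called 20, and with an estimated correlation camera called 0, the smallest adjusted p with an estimated correlation being 0.146. Fry did not call the oxidative phosphorylation, proteasome and dendritic cell lists (fry adjusted p = 0.288, 0.103 and 0.097). It called the apoptosis and the cytokine receptor lists (fry adjusted p = 0.03 and 0.00331), which camera did not call. The 19 lists that camera with a preset correlation did not call had a camera adjusted p of 0.0622 to 0.968. The count of 2289 features became 570 in a model with interactions (86.7% of them higher in aged mice, against 57.8%), 1185 without scaling between arrays, 3791 with another background correction (48.4% higher), 5110 with array weights (46.1% higher), 1183 with age as the sole term, 1259 with a looser filter on dim probes, 738 with no filter (80.6% higher), and 1 with the mean of the B cell list or of the macrophage list as a covariate. In the same test it was 429 without Young_WT, 278 without Young_WT with tumor, 632 without Young_PD-1KO, 445 without Young_PD-1KO with tumor, 258 without Aged_PD-1KO and 528 without Aged_PD-1KO with tumor, of which between 77.5% and 90.3% were higher. Over features with a gene symbol alone, 1009 were higher and 1150 lower. Young arrays lay in row 1 and aged arrays in row 2 of the slide, so age and slide row cannot be told apart.

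**Figure D2:**
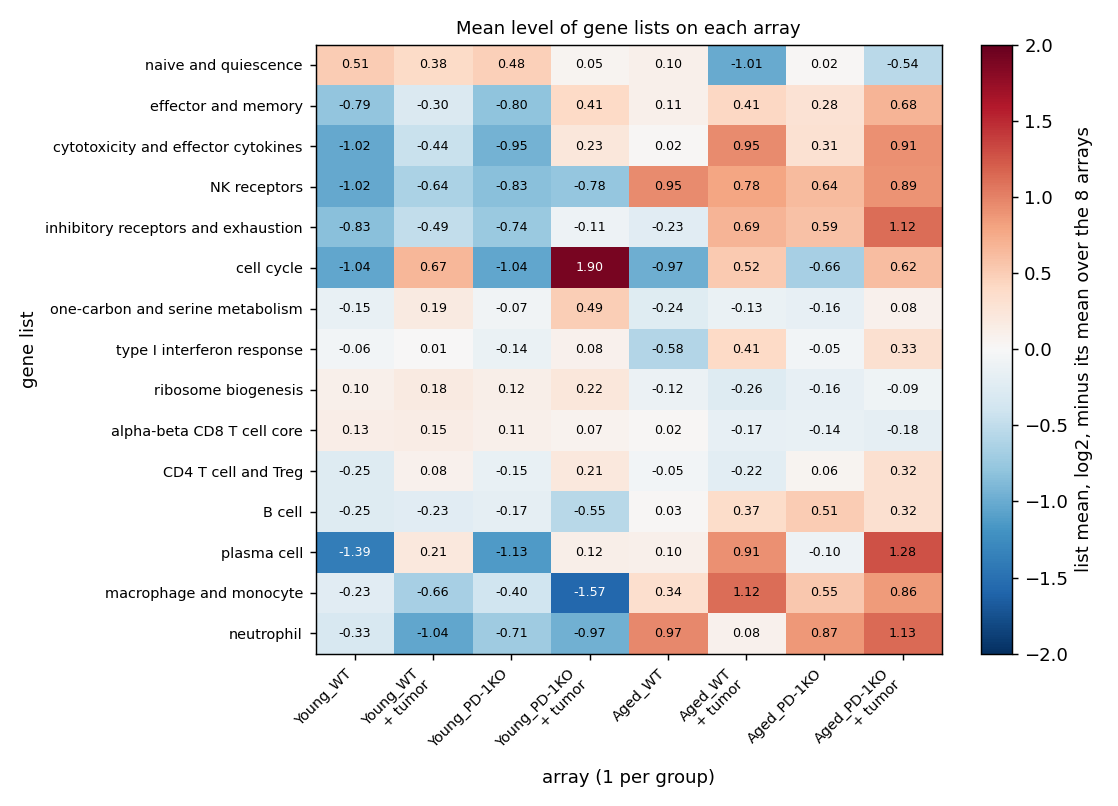
Mean log2 level of 15 gene lists (y axis) on each of the 8 arrays (x axis, 1 array per group), each list centred on its own mean over the arrays, with red above and blue below that mean and the value printed in each cell. The NK receptor list lies at 0.64 to 0.95 on the aged arrays and at -1.02 to -0.64 on the young arrays, and the cell cycle list lies at 0.52 to 1.90 on the tumor arrays and at -1.04 to -0.66 on the tumor-free arrays.

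The comparison of tumor-bearing with tumor-free mice gave no single gene past the threshold, while cell cycle genes were higher as a group by camera with a preset correlation (adjusted p = 0.387 with an estimated correlation) and so was the plasma cell list, with a median of 1.27 (adjusted p = 0.224 with an estimated correlation). Ccna2 and Ccnb1, cyclins of the S and M phases, stood 2.76 (SE 0.36) and 2.66 (SE 0.37) higher in the draining nodes of tumor-bearing mice, and Kif2c, a mitotic kinesin, was at least 4.95-fold higher in them, each with an adjusted p of 0.0549 and in 4 of 4 pairs. Gzma and Gzmb, granzymes of killer T cells, stood 3.67 (SE 0.67, adjusted p = 0.0697) and 3.25 (SE 0.69, adjusted p = 0.0903) higher. Popdc2 stood 3.84 higher (SE 0.72, adjusted p = 0.074), Galnt3, a glycosyltransferase gene, 3.47 higher (SE 0.77, adjusted p = 0.0961), and the nonagouti gene (symbol a) was at least 2.92-fold higher (adjusted p = 0.0842). Differences in the other direction were -2.30 for Cd209e (SE 0.19, adjusted p = 0.0549) and -2.05 for Cd209a (SE 0.26, adjusted p = 0.0549), both C-type lectins of myeloid cells. Bpifb2 was at least 2.70-fold lower (adjusted p = 0.0571), Bpifb3 stood at -1.96 (SE 0.46, adjusted p = 0.104) and Sorcs2 at -1.73 (SE 0.64, adjusted p = 0.206). All 4 pairs had the same sign for each of these genes. The rule for naming genes required this of all but Ccna2, Ccnb1 and Kif2c. Popdc2 and Galnt3 were each well above background on 1 tumor-free and 4 tumor arrays and Sorcs2 on 4 and 3, so their sizes rest in part on background.

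Of 45 measured cell cycle genes, 45 were above 0 and 0 passed over all genes, while adjusted over the list alone 44 rose and 0 fell. The median log2 difference was 2.11 (camera adjusted p = 3.57e-41, adjusted p = 0.387 with an estimated correlation), and the list mean was 1.71 higher in young WT, 2.94 in young PD-1KO, 1.49 in aged WT and 1.29 in aged PD-1KO mice. On the same arrays the plasma cell list was higher by a median of 1.27, in 4 of 4 pairs. Among the T cell programs, none of whose members passed over all genes, effector and memory genes had a median of 0.47, with Lgals3 at 2.43 and Lgals1 at 1.79. Of these 31 genes, adjusted over the list alone, 13 rose and 0 fell (camera adjusted p = 2.71e-09, adjusted p = 0.387 with an estimated correlation). Cytotoxicity genes had a median of 0.32, with Gzmk at 3.15. Of these 20 genes, adjusted over the list alone, 9 rose and 0 fell (camera adjusted p = 2.39e-05, adjusted p = 0.224 with an estimated correlation). Inhibitory receptor genes had a median of 0.52, with Havcr2 (TIM-3) at 2.10 and Lag3 at 1.54. Of these 21 genes, adjusted over the list alone, 9 rose and 0 fell (camera adjusted p = 4.5e-06, adjusted p = 0.349 with an estimated correlation). Naive genes had a median of -0.50, with Igfbp4 at -1.63 and Ramp1 at -1.28. Of these 20 genes, adjusted over the list alone, 0 rose and 7 fell (camera adjusted p = 1.1e-05, adjusted p = 0.48 with an estimated correlation). Tissue residency genes had a median of -0.34, with Ccr9 at -0.92. Of these 17 genes, adjusted over the list alone, 0 rose and 1 fell (camera adjusted p = 0.0361, adjusted p = 0.693 with an estimated correlation).

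Of the interferon and stress programs, 6 were higher with tumor by smaller amounts, by camera with a preset correlation, with 0 members past the threshold over all genes. The type I interferon list had a median of 0.47, with Ly6a at 1.09 and Oas3 at 0.75. Of these 36 genes, adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 2.32e-09, adjusted p = 0.48 with an estimated correlation). The list mean differed by 0.07 in young WT, 0.22 in young PD-1KO, 0.99 in aged WT and 0.38 in aged PD-1KO mice. On the tumor-free Aged_WT array the centred list mean was -0.58, against -0.14 to -0.05 on the other tumor-free arrays. The aged WT difference therefore rests in part on that low array. The interferon-gamma list had a median of 0.18, with Gbp3 at 0.75. Of these 26 genes, adjusted over the list alone, 0 rose and 0 fell (camera adjusted p = 0.00058, adjusted p = 0.48 with an estimated correlation). Inflammation and senescence genes had a median of 0.14, with Cdkn2a, which encodes cell cycle inhibitors, at 1.58 and Il10 at 1.54. Of these 21 genes, adjusted over the list alone, 7 rose and 0 fell (camera adjusted p = 0.00454, adjusted p = 0.349 with an estimated correlation). Apoptosis and survival genes had a median of 0.10, with Bcl2a1d at 0.58. Of these 21 genes, adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 0.0172, adjusted p = 0.349 with an estimated correlation). Genes of the unfolded protein response had a median of 0.19, with Sdf2l1 at 0.99 and Creld2, which the plasma cell list also holds, at 0.52. Of these 23 genes, adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 8.72e-05, adjusted p = 0.454 with an estimated correlation), and the plasma cell median was 1.27 on the same arrays. Antioxidant genes had a median of 0.08, with Txn1 at 0.55. Of these 22 genes, adjusted over the list alone, 0 rose and 0 fell (camera adjusted p = 0.00454, adjusted p = 0.48 with an estimated correlation). The immediate early and heat shock list, at -0.13 with 20 of 29 genes below 0, the p53 list, at -0.01, and the autophagy list, at 0.02, did not pass (camera adjusted p = 0.311, 0.637 and 0.35).

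Several metabolic groups and the plasma cell markers were higher with tumor as well, by camera with a preset correlation. Glycolysis genes had a median of 0.28, with the lactate transporter gene Slc16a3 at 1.34. Of these 22 genes, adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 1.1e-05, adjusted p = 0.454 with an estimated correlation). One-carbon genes had a median of 0.17, with the thymidylate synthase gene Tyms at 1.95. Of these 26 genes, adjusted over the list alone, 5 rose and 0 fell (camera adjusted p = 0.000417, adjusted p = 0.48 with an estimated correlation). Proteasome genes had a median of 0.23, with all 32 measured above 0 and Psma4 at 0.48 (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 6e-09, adjusted p = 0.48 with an estimated correlation). Oxidative phosphorylation, cholesterol and TCA cycle lists had medians of 0.15, 0.15 and 0.06 (camera adjusted p = 5.56e-07, 0.0257 and 0.0361, adjusted p = 0.672, 0.702 and 0.672 with an estimated correlation), and in each of them 0 genes rose and 0 fell, adjusted over the list alone. Fatty acid oxidation, at 0.04 with 2 of 4 pairs above 0, and amino acid transport with ATF4 targets, at 0.07, did not pass (camera adjusted p = 0.297 and 0.123). Plasma cell markers had a median of 1.27, with Jchain at 2.16, Mzb1 at 2.09 and Derl3 at 1.60. Of these 6 genes, adjusted over the list alone, 5 rose and 0 fell (camera adjusted p = 7.12e-07, adjusted p = 0.224 with an estimated correlation). The macrophage and B cell lists, at -0.19 and -0.16, did not pass for tumor (camera adjusted p = 0.616 for both).

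In limma, 0 of 21232 features passed for tumor, with 4370 at an unadjusted p under 0.05 against 1061.6 by chance, a smallest adjusted p of 0.0549 and 755 features at an adjusted p under 0.1. Camera with a preset correlation called 19 of 40 lists, 17 higher and 2 lower, fry called 3 (plasma cell, cytotoxicity, and apoptosis and survival) and camera with an estimated correlation called 0, while the other 21 lists had a camera adjusted p of 0.053 to 0.89. The count of 0 became 108 after quantile normalization, 282 without scaling, 223 with another background correction, 280 with a stricter filter on dim probes, 107 with the mean of each gene's probes, 246 with the authors' values, 95 with tumor as the sole term, 1693 with array weights, 331 with an intensity trend, 361 with the macrophage list mean as a covariate, 206 over features with a gene symbol alone, and 186 without Young_PD-1KO with tumor. Leaving out 1 array ended the calls of the TCA cycle list (without Young_WT, Young_WT with tumor, Young_PD-1KO or Young_PD-1KO with tumor, medians 0.03 to 0.05), the cholesterol list (without Young_PD-1KO or Young_PD-1KO with tumor, 0.08 and 0.07), the tissue residency list (without Young_WT, Aged_WT or Aged_WT with tumor, -0.34, -0.26 and -0.20) and the apoptosis list (without Aged_WT, 0.09). Tumor-bearing mice gave draining nodes and tumor-free mice peripheral nodes, so tumor and node cannot be told apart. Tumor-free arrays lay in columns 1 and 3 and tumor arrays in columns 2 and 4 of the slide. Tumor and slide column cannot be told apart either.

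The comparison of PD-1KO with WT mice addresses the part played by PD-1. Ctse, which encodes the aspartic protease cathepsin E, was 19.2-fold higher in PD-1KO mice, a log2 rise of 4.26 (SE 0.14, adjusted p = 0.000394). Ren1, which encodes renin, was at least 3.84-fold higher, being well above background on 4 PD-1KO arrays and 0 WT arrays (adjusted p = 0.00223). Il10, an anti-inflammatory cytokine gene, rose by 2.19 (SE 0.16, adjusted p = 0.0278) and was well above background on 2 WT arrays and 4 PD-1KO arrays. Fcer1a, a chain of the high-affinity IgE receptor, fell by 1.03 (SE 0.09, adjusted p = 0.0417) and was well above background on 3 WT arrays and 1 PD-1KO array. These 4 genes, each read by 1 probe, all lie on chromosome 1, as does Pdcd1. Each moved the same way in 4 of 4 pairs, as the rule for naming genes required. In limma 6 of 21232 features passed, 4 higher and 2 lower, with 2206 at an unadjusted p under 0.05 against 1061.6 by chance.

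**Figure D3:**
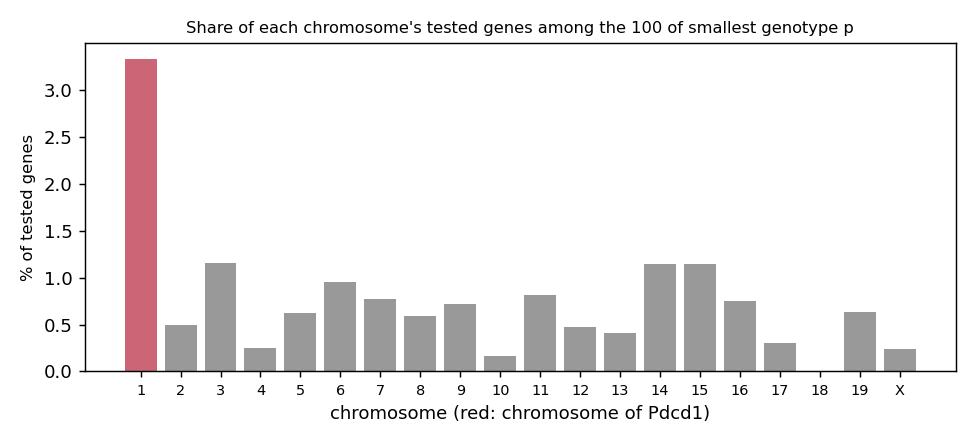
Share of the tested genes of each chromosome (x axis) that are among the 100 genes with the smallest unadjusted p for genotype (y axis, percent), with the chromosome that holds Pdcd1 in red. Of these 100 genes, 24 lie on chromosome 1, which holds 5.61% of the tested genes.

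No member of the 13 lists that camera called for genotype passed over all genes, and adjusted over the list alone 1 gene rose, Ly6a in the type I interferon list, and 0 fell. Cell cycle genes had a median of 0.38, with Cdk1 at 1.18 and Cdc45 at 0.90 (camera adjusted p = 6.12e-09, adjusted p = 0.724 with an estimated correlation), and their list mean was 1.23 higher in young tumor-bearing PD-1KO mice against a difference of -0.000507 in young tumor-free mice. Inhibitory receptor genes had a median of 0.37, with Havcr2 at 1.07, Lag3 at 1.05 and Tigit at 0.95 (camera adjusted p = 9.1e-06, adjusted p = 0.724 with an estimated correlation). Effector and memory genes had a median of 0.35, with S100a6 at 0.83 (camera adjusted p = 0.000183, adjusted p = 0.724 with an estimated correlation). Cytotoxicity genes had a median of 0.19, with Gzmk at 1.34 and Ccl3 at 1.18, and chemokine receptors and integrins one of 0.21, with Ccr10 at -1.94 (camera adjusted p = 0.0219 for both, adjusted p = 0.724 for both with an estimated correlation). The interferon-gamma list had a median of 0.12, with Iigp1 at 0.99 (camera adjusted p = 0.00436, adjusted p = 0.724 with an estimated correlation). The type I interferon list had a median of 0.11, with Ly6a at 1.06 (camera adjusted p = 0.0219, adjusted p = 0.727 with an estimated correlation), which turned to -0.09 without Aged_WT. One-carbon, cholesterol, glycolysis and TCA cycle lists had medians of 0.13, 0.11, 0.11 and 0.06 (camera adjusted p = 0.00353, 0.00436, 0.0362 and 0.0452, adjusted p = 0.724 for each with an estimated correlation). The proteasome list had a median of 0.07 and the ribosomal protein list one of -0.10, with Rps20 at -0.94 (camera adjusted p = 0.0219 and 0.0421, adjusted p = 0.727 for both with an estimated correlation). The ribosomal protein median turned to 0.0455 after quantile normalization and to 0.045 with the authors' values.

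For genotype, camera with a preset correlation called 13 of 40 lists, 12 higher and 1 lower, while fry and camera with an estimated correlation called 0 and the other 27 lists had a camera adjusted p of 0.0511 to 0.875; 8 were called without Young_WT with tumor and 8 without Young_PD-1KO with tumor. Of the 13, the number that lost their call was 3 without Young_WT, 6 without Young_WT with tumor, 3 without Young_PD-1KO, 7 without Young_PD-1KO with tumor, 3 without Aged_WT (and the type I interferon list, which changed sign there), 3 without Aged_WT with tumor, 5 without Aged_PD-1KO and 2 without Aged_PD-1KO with tumor, while the cell cycle, inhibitory receptor, and effector and memory lists stayed called without any 1 array. Among these losses, the cytotoxicity median went to 0.0377 without Young_WT with tumor and to 0.0651 without Young_PD-1KO with tumor, and that of type I interferon to 0.0323 without Young_WT with tumor. Without Young_PD-1KO with tumor the glycolysis, proteasome, TCA cycle, cholesterol and one-carbon medians went to 0.00864, 0.00452, 0.0367, 0.0441 and 0.0839. The ribosomal protein median went to -0.00841 without Aged_WT, the interferon-gamma median to 0.0409 without Aged_PD-1KO and the chemokine receptor median to 0.085 without Aged_WT with tumor. The gene count of 6 became 0 with interactions in the model and 0 without the features on chromosome 1, 1 with another background correction, 19 with array weights, 3 with an intensity trend, and 2 with a looser or stricter filter or none, with genotype as the sole term, with either covariate and with the authors' values. It was 3 without Aged_WT with tumor and 2 without any other single array, where Il10 and Fcer1a did not pass. WT arrays lay in columns 1 and 2 and PD-1KO arrays in columns 3 and 4 of the slide. Genotype and slide column therefore cannot be told apart.

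The interactions ask whether the age difference depends on tumor or on PD-1 and whether the tumor difference depends on PD-1. In limma, 0 features passed for age by tumor, 0 for age by genotype and 0 for genotype by tumor, with 863, 604 and 680 at an unadjusted p under 0.05 against 1061.6 by chance, the smallest adjusted p over the 3 tests being 0.992. On simulated data with an interaction of 2 on the log2 scale in 200 features, the same test recovered 0% for each of the 3. An interaction of that size was therefore not detectable by this test, which leaves 1 residual degree of freedom. The simulated noise was that of the additive fit. A model with the 3 factors and the tested interaction alone was not simulated. Left-out arrays gave 3 features for age by tumor without Aged_WT with tumor, 1 for age by genotype without Aged_PD-1KO, and 1 and 2 for genotype by tumor without Young_PD-1KO with tumor and without Aged_PD-1KO with tumor.

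Single pairs of arrays that differ in 1 factor show how far the differences recur, without a test. Age gave 970 features at least 2-fold apart in tumor-free WT mice, 1292 in tumor-free PD-1KO, 3344 in tumor-bearing WT and 2107 in tumor-bearing PD-1KO mice, and 265 features were at least 2-fold higher and 33 at least 2-fold lower in all 4 pairs. For tumor there were 824 in young WT, 1776 in young PD-1KO, 1947 in aged WT and 868 in aged PD-1KO mice, with 177 higher and 10 lower in all 4 pairs. Genotype gave 291, 1052, 689 and 1997 in young tumor-free, young tumor-bearing, aged tumor-free and aged tumor-bearing mice, with 8 higher and 5 lower in all 4 pairs. All 4 pairs had the same sign for 45.4% of features with age, 30.8% with tumor and 21.9% with genotype, against 12.5% by chance. Pearson's r across features between pairs that share no array, where features are not independent replicates, ran from 0.496 to 0.633 for age, from 0.145 to 0.655 for tumor and from 0.0896 to 0.231 for genotype. For tumor, the values with the aged WT pair were 0.182, 0.343 and 0.145.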

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

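The tests of explanations, of chromosomes and of list interactions in this part were chosen only after the results were seen. The 35 splits were planned, but how their counts would be read was set after. The bound for the NK receptor test was made stricter after its value was seen.

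Markers of macrophages, neutrophils, B cells and plasma cells were higher on aged arrays, together with the NK receptor and effector lists. A lower share of CD8 T cells in the aged samples could raise markers of other cell types. The CD8 T cell core list had a mean shift of -0.233, below 0 in 4 of 4 pairs. The macrophage list rose 0.823 more than the B cell list (SD 0.648 over 4 pairs, above 0 in 4 of 4). The CD4 list had a mean shift of 0.06, with 4 of its 8 genes above 0 and 4 below. These unequal shifts do not decide it, since a lower share raises other markers alike only if the other cells keep their mix. Of the macrophage genes, Apoe stood at 2.42 to 4.86 over the arrays and rose with age by 1.18 (SE 0.24, adjusted p = 0.0361), while Itgam stood at 4.32 to 5.29 and did not rise (-0.03, SE 0.20, adjusted p = 0.936). With the macrophage list mean as a covariate, the median NK receptor shift was 1.66 (list mean 1.80, 95% interval 1.03 to 2.57, against 1.63 without it), so it did not fall. As that covariate follows age closely, the fit separates macrophage RNA from age only weakly and does not settle the source of the NK receptor rise. That covariate also took the count of genes from 2289 to 1, as r squared between it and age was 0.742, the median SE went from 0.138 to 0.268 and the median size of the 2289 changes from 0.80 to 0.58, with 2280 of them keeping their sign. A lower share of CD8 T cells and macrophage RNA as a source both stay open. A change in the macrophages or in age itself stays open and untested, and the CD8a bead selection is meant to remove such cells. Slide row cannot be told apart from age because 0 slide rows hold both ages.

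The 4 named genes called for genotype lie on chromosome 1, which also holds Pdcd1. A candidate explanation is DNA flanking the Pdcd1 deletion that came from another strain, which predicts an excess of genotype differences on that chromosome. Of the 100 genes with the smallest genotype p, 24 lie there, against 5.61% of tested genes (odds ratio 5.46, 95% interval 3.27 to 8.80, Fisher's exact 2-sided p = 9.1e-10), but age gave 13 of 100 (odds ratio 2.54, 1.29 to 4.60, exact p = 0.00384) and tumor 9 of 100 (1.67, 0.737 to 3.33, exact p = 0.183), so some of the excess may be unrelated to genotype. A variant under the probe cannot be told apart from a change in level, because 0 of the called genes have another passing probe. An effect of PD-1 on these genes stays open and was not tested apart from the flanking DNA or from the slide column.

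No gene passed for tumor, although cell cycle genes were higher as a group by camera with a preset correlation (adjusted p = 0.387 with an estimated correlation) and plasma cell markers were higher on the same arrays, with a median of 1.27 in 4 of 4 pairs. Whether plasma cells added to the cell cycle rise was not tested and stays open. The aged WT pair correlated least with the other tumor pairs, yet 0 genes passed for tumor without the Aged_WT with tumor array and 0 without the Aged_WT array, while leaving out Young_PD-1KO with tumor gave 186. This decides neither array, as an array less also costs a degree of freedom, and the features at an unadjusted p under 0.05 went from 4370 to 5536 without Aged_WT with tumor and to 4186 without Aged_WT. A difference between draining and peripheral nodes, or between responses to tumor by age or genotype that widen the error of the additive model, stays open; the interaction tests recovered 0% of simulated changes of 2, for age by tumor and for genotype by tumor alike.

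The counts were compared with those of all 35 splits of the 8 arrays into 4 and 4, each split being the sole term. For genes changed with age, 1 of 35 splits, the real one, gave as many as 1183, the highest of the others being 95. This does not exclude chance, as 1 of 35 is the smallest share the test can give. Splits across age also put the age difference into their error, and the split by age is the split by slide row. For genes changed with tumor, 2 of 35 splits gave as many as 95, the highest of the others being 1183 for the split by age, which points to age as a structure of the samples. For genes changed with genotype, 3 of 35 splits gave as many as 2, the highest again being 1183. The splits as large as those for tumor and genotype genes were the factors themselves, and the 32 splits that follow no factor gave at most 1 gene, so the shares of splits count the other factors as chance and do not decide it for these gene counts. For gene lists, 6 of 35 splits gave as many as 21 for age, 11 as many as 18 for tumor and 27 as many as 10 for genotype, the highest of the others being 25 in each, so chance could not be excluded for any of the list counts.

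In 180 sets of 4 arrays of one level, 9 had 1 array beyond the critical value of Dixon's test, where chance gives about 9 (1 in 20). The ratio of the gap to the range was 0.8293 for the CD8 T cell core list on Aged_WT among aged arrays, 0.9144 for the NK cell list on Young_WT with tumor among young arrays, 0.883 for Ret on Young_PD-1KO with tumor among young arrays, 0.8503 for Lmo1 and 0.9077 for Dpysl5 on Aged_WT among aged arrays, and 0.8858 for Abcb11 on Aged_PD-1KO among aged arrays. It was 0.8968 for the cell cycle list on Young_PD-1KO with tumor among tumor arrays, 0.8305 for the type I interferon list on Aged_WT among tumor-free arrays, and 0.8509 for the proteasome list on Young_WT with tumor among WT arrays.

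Some lists differed between groups in the size of an effect by camera with a preset correlation, in the model with all 3 interactions. With an estimated correlation, in a model of the 3 factors and the tested interaction alone, none of 40 lists passed. The smallest adjusted p with an estimated correlation was 0.612 for age by tumor, 0.94 for age by genotype and 0.905 for genotype by tumor. For age by tumor, where 13 lists passed (4 higher, 9 lower), the median interaction was -0.357 for naive, -0.416 for effector and memory, 0.155 for inhibitory receptor, -1.01 for cell cycle, -0.241 for one-carbon, -0.242 for oxidative phosphorylation, -0.162 for TCA cycle, -0.232 for cholesterol, 0.46 for type I interferon, -0.276 for proteasome, -0.277 for ribosomal protein, 0.245 for B cell and 1.17 for macrophage genes. For age by genotype, where 9 passed (8 higher, 1 lower), it was 0.264 for naive, 0.422 for inhibitory receptor, 0.232 for tissue residency, -0.451 for cell cycle, 0.249 for type I interferon, 0.151 for interferon-gamma, 0.359 for B cell, 0.486 for macrophage and 0.767 for neutrophil genes. For genotype by tumor, where 15 passed (12 higher, 3 lower), it was 0.387 for effector and memory, 0.21 for TCR stimulation, 0.289 for tissue residency, 0.492 for cell cycle, 0.243 for one-carbon, 0.2 for oxidative phosphorylation, 0.277 for cholesterol, -0.266 for type I interferon, 0.274 for unfolded protein response, 0.356 for chemokine receptor, 0.22 for proteasome, 0.167 for ribosomal protein, -0.342 for B cell, -0.614 for macrophage and 0.595 for neutrophil genes.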

How the results depend on the processing

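The macrophage covariate, the fit over features with a gene symbol alone and the fit without the chromosome of Pdcd1 were chosen after the data were seen; all other alternatives were fixed before. The labels pair no arrays within a group, and a fit that blocks on the 4 pairs of a factor was not run. Normexp was run on the median signal, as the files hold no mean signal, and the fit of array weights stopped before it reached its convergence tolerance. A left-out array leaves 7 arrays, and the lone arrays are assumed to vary like the others. No scaling moved the median of all features by over 0.1. Signal over background limits genes near the floor. Folds are lower bounds where no array of a level was well above background; where only some were, the differences rest in part on background.

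The 2289 genes for age became 1185 without scaling, 3791 with normexp, 1259 with probes well above background on at least 1 array, 738 with no filter, 1183 with age alone, 570 with interactions and 5110 with array weights, and the cause was not tested. The share of calls that were higher in aged mice, 57.8%, was 48.4% with normexp, 46.1% with array weights, 48.5% with an intensity trend, 46.7% with symbols alone, 50.6% with probes well above background on all 8 arrays, 64.6% with age alone, 68.9% with the looser filter, 80.6% with no filter, 86.7% with interactions and 57.7% to 90.3% with an array left out. With the B cell or the macrophage covariate the count was 1, where the SE about doubled (0.138 to 0.276 and 0.268) and sizes fell. Leaving out arrays, it ran from 258 without Aged_PD-1KO to 2324 without Aged_WT, with 429 without Young_WT, 278 without Young_WT with tumor, 632 without Young_PD-1KO, 445 without Young_PD-1KO with tumor and 528 without Aged_PD-1KO with tumor. Quantile normalization (1987) and the authors' values (2075) stayed within 1.5 times.

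The 0 genes for tumor became 108 with quantile normalization, 282 without scaling, 223 with normexp, 280 with probes well above background on all 8 arrays, 107 with the mean of probes, 246 with the authors' values, 95 with tumor alone, 1693 with array weights, 331 with an intensity trend, 361 with the macrophage covariate and 206 with symbols alone. The count was 0 with the looser filter, no filter, interactions or the B cell covariate, and from 0 to 186 with an array left out (186 without Young_PD-1KO with tumor); the smallest adjusted p was 0.0549 and the cause was not tested.

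The 6 genes for genotype became 1 with normexp, 2 with either other filter, no filter, the authors' values, genotype alone or either covariate, 3 with an intensity trend, 19 with array weights, 0 with interactions and 0 without the chromosome of Pdcd1, which by its construction removes 4 of the 6, while the others lost their call (smallest adjusted p 0.0732); the cause was not tested. They ran from 2 to 3 with an array left out (3 without Aged_WT with tumor). The interactions gave 0 under every alternative but left-out arrays: 0 to 3 for age by tumor (3 without Aged_WT with tumor), 0 to 1 for age by genotype (1 without Aged_PD-1KO) and 0 to 2 for genotype by tumor (1 without Young_PD-1KO with tumor, 2 without Aged_PD-1KO with tumor).

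The counts of lists, 21 for age, 19 for tumor and 13 for genotype, became 0, 0 and 0 with an estimated correlation, and with fry 20, 3 and 0. Of the 21 lists for age, 3 lost their call with fry. The cause was not tested. With arrays left out they ran from 17 to 25 for age, from 18 to 22 for tumor and from 8 to 14 for genotype (8 without Young_WT with tumor and 8 without Young_PD-1KO with tumor). With the macrophage covariate, medians for age turned to 0.049 (one-carbon), 0.149 (oxidative phosphorylation), 0.0529 (proteasome) and -0.0395 (dendritic cell). A further 7 lists for age kept their direction but lost their call with that covariate. The same held for 5 lists for age with quantile normalization and 4 with the authors' values. For genotype, the ribosomal protein median turned to 0.0455 with quantile normalization and 0.045 with the authors' values, and the type I interferon median, which ran from -0.0931 to 0.23 with an array left out, to -0.0931 without Aged_WT; the cause was not tested. Of all list medians, these included, 279 of 335 values for age, 250 of 304 for tumor and 136 of 208 for genotype kept direction and side of the threshold, and 52, 54 and 69 kept the direction alone. Of named genes, 340 of 459 for age and 74 of 109 for genotype kept both, 119 and 35 kept the direction alone, and for tumor 200 of 243 stayed short of the threshold and 43 passed it.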

Other observations

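The red blood cell list was not tested, as only 4 of its 12 fixed genes were measured, of which Hbb-bt rose with age (3.71, adjusted p = 0.0489). The list mean, centred over the arrays, was 3.71 on Aged_WT, and Hbb-bt stood at 3.26 there against -5.60 to -0.96 on the other arrays. Without Aged_WT, the count of genes changed with age was 2324.

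Of genes linked to sex, Xist was well above background on all 8 arrays, at -1.54 to -0.26, and Ddx3y on 0 of them. Xist rose with age by 0.74 (adjusted p = 0.0388). Among gamma-delta and NKT cell genes, 2 of 12 were measured, and Cd163l1 stood at -0.03 on Aged_WT with tumor against 1.40 to 2.62 on the other arrays. Among tumor cell (epithelial) genes, 5 of 13 were measured, and neither that list nor the stromal list passed for tumor (camera adjusted p = 0.89 and 0.311, medians -0.11 and -0.27).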
